A study of Mus musculus with 82 samples.

How the data were processed

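Total RNA from quick-frozen mouse sciatic nerve was made into stranded, poly(A)-selected libraries and sequenced, per the labels' protocols. The deposited values are estimated counts per gene, made by the authors with kallisto, a tool that assigns reads to transcripts without aligning them, on the mouse build mm10, per the submitters' processing notes. The versions, the transcript annotation and the step from transcripts to genes are not given in the sources used here. Exactly whole values, zeros included, made up between 34.79% and 89.04% of a table, and the estimated counts were rounded before any test. The 8 tables, called here by their experiment, differ in length: 51444 genes for Fig4 at P12, for the injury table and for the time course, 53278 for Fig4 at P4, DhhCre and Egr2Cre, 31232 for Egr2Cre Mitf and 18003 for the table with Ndrg1. A gene missing from a shorter table was not analysed there. Columns not used numbered 0. Each table was tested within itself, except that the P12 and P4 Fig4 tables entered 1 fit over their 26414 shared symbols, in which differences within each table were contrasted. Positions of the targeted genes, transcript lengths and GC content are those of GENCODE vM21 on mm10, matched by symbol.

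The tests were fixed before the data were examined. Genes passed edgeR's filterByExpr (minimum count 10), were scaled by TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), two-sided, with Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. Fold changes are log2, the first-named group minus the second, and the SE is the absolute log2 change divided by the square root of the test's F. Comparisons of the time course and of the table with Ndrg1 shared 1 estimate of the spread over all groups of the table. The 17 comparisons included 3 interactions. The levels printed as CPM, counts scaled to library size, were computed from the deposited estimated counts, and log2 CPM used a pseudocount of 2. No pair of replicates of a group held the same library: the lowest chi-square per degree of freedom over genes with a mean count of at least 20 was 9.376.

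Lists of genes were also fixed before the data were examined: 13 gene lists (myelin, cholesterol synthesis, repair Schwann cell, non-myelinating Schwann cell, lysosome, pigment cell, cell cycle, integrated stress response, glycolysis, interferon response, immediate early and heat shock, extracellular matrix, and axon-induced growth factor and Neuregulin signalling) and 11 marker lists of other cell types (macrophage, neutrophil, mast cell, lymphocyte, endothelial, pericyte and smooth muscle, fibroblast, perineurial, adipocyte, skeletal muscle and erythrocyte). Some genes are in several lists. Lists with at least 3 measured members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Cross-table sets held genes with adjusted p under 0.05 and an absolute log2 change of at least 1 in the injury table, in Ndrg1 against control or in Fig4 at P12, and were tested in comparisons of other tables, so that no library served both. Comparisons against the same controls in the table with Ndrg1 were not compared by overlap; the direct contrast, the interaction and a split of the libraries by odd and even number were used.

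The genes named were fixed by rule: Fig4, Mitf and Ndrg1; per direction the 8 genes with the smallest p among those past the test with an absolute log2 change of at least 1 and a mean of at least 1 CPM, leaving out predicted, clone, pseudogene and sex-linked names (without the fold minimum where fewer than 8 passed); the 4 members of each list with the smallest p, and other list members where needed to describe a list. Some genes that this rule names are not reported here. Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, the replicate number as a block, a sex covariate from Y-linked counts, a fit of the compared groups alone, each replicate left out, and the estimated correlation. A skeletal muscle covariate and the removal of muscle-rich libraries were added after seeing the data. Replicate numbers were checked by the correlation of deviations from the group means. Every pair was over 0.1, a hint of pairing, in DhhCre (0.119 to 0.299) and Egr2Cre Mitf (0.123 to 0.34). In DhhCre 3 of 5 were best with their own number.

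Each comparison was tested on simulated counts with 200 changed genes. At a true change of 2-fold and 4-fold the test recovered 51% and 84% of changed genes for Fig4 at P12, 7% and 74% at P4, 9% and 57% for the difference between the ages, 30% and 70% for injury, 27% and 79% for genotype by time, and between 52% and 91% (2-fold) and between 90% and 99% (4-fold) in the other comparisons. Between 3 and 18 unchanged genes were called. The signs of recovered genes were right in 100%.

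Xist and the Y-linked gene Ddx3y both reached 1 CPM in 28 of the 82 libraries, so these libraries held counts of both; the labels do not speak of pooling.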

Results

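RNA was sequenced from 82 mouse sciatic nerve libraries, which fell into 22 groups and were deposited as 8 count tables. The sciatic nerve holds Schwann cells, the glia that wrap axons in myelin, together with fibroblasts, macrophages, vessels, fat and the cells of the perineurial sheath. One table compared Fig4 -/- with Fig4 +/+ nerves at postnatal day 12 (P12), and another compared the same genotypes at P4, with 3 libraries in each group. Fig4 is a phosphoinositide phosphatase whose loss disturbs the late endosome and lysosome and causes a degeneration of neurons. A table at P21 held 5 libraries labelled DhhCre and 5 labelled Mitf, and a table at P12 held 3 labelled Egr2Cre and 3 labelled Mitf. Dhh and Egr2 are genes of the Schwann cell lineage whose regulatory regions are used to drive Cre recombinase. A further table held 4 uninjured nerves and 4 nerves taken 3 days post injury, all of them labelled Mitf. The next held wild type and Mutant nerves 3, 7 and 14 days post injury, with 3 libraries in each group. A table without an age or injury in its labels held 3 libraries labelled Egr2Cre Mitf and 3 labelled Mitf. The last, likewise, held 6 control, 6 Mitf, 5 Ndrg1 and 5 Mitf-Ndrg1 libraries. Mitf is a transcription factor of the MiT/TFE family, known from pigment cells and lysosomal gene control, and Ndrg1 is a cytoplasmic protein abundant in myelinating Schwann cells whose loss causes a demyelinating neuropathy. The labels did not say which of the lone labels Mitf, DhhCre, Egr2Cre and Mutant carried an altered Mitf gene, so directions are given by label throughout. Total estimated counts ran from 15440000 to 34530000 per library. The labels did not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

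Fig4 (ENSMUSG00000038417.4, chromosome 10, 41188172 to 41303260, minus strand) stood at 4.7 ± 1.59 CPM (counts scaled to library size; SD, n = 3) in Fig4 -/- nerves at P12 against 21.4 ± 3.61 in Fig4 +/+ nerves. At P4 the values were 4.47 ± 0.286 and 30.1 ± 2.12 CPM (SD, n = 3 each). Outside these groups Fig4 lay between 13.8 ± 3.24 CPM in wild type nerves 14 days post injury (SD, n = 3) and 28.6 ± 2.69 CPM in uninjured nerves labelled Mitf (SD, n = 4). Ndrg1 (ENSMUSG00000005125.13, chromosome 15, 66929318 to 66969640, minus strand) stood at 192 ± 16.4 CPM in Ndrg1 libraries and 196 ± 12.3 CPM in Mitf-Ndrg1 libraries (SD, n = 5 each), against 1840 ± 64.2 CPM in controls and 1660 ± 170 CPM in libraries labelled Mitf (SD, n = 6 each). Mitf (ENSMUSG00000035158.15, chromosome 6, 97807052 to 98021349, plus strand) was lower in the DhhCre libraries at P21, at 5.7 ± 1.14 CPM (SD, n = 5), than in the libraries labelled Mitf of that table, at 19.8 ± 2.1 CPM (SD, n = 5). At P12 it stood at 8.5 ± 1.67 CPM in Egr2Cre and 13.9 ± 0.287 CPM in Mitf libraries (SD, n = 3 each). In the table without an age it stood at 8.27 ± 1.47 CPM in Egr2Cre Mitf and 10.6 ± 0.531 CPM in Mitf libraries (SD, n = 3 each). In the table with Ndrg1 it stood at 16.8 ± 1.73 CPM in controls, 11.5 ± 1.49 in Mitf (SD, n = 6 each), 19.7 ± 2.93 in Ndrg1 and 16.8 ± 2.79 in Mitf-Ndrg1 libraries (SD, n = 5 each). In the time course Mitf ran from 3.54 ± 1.43 CPM in Mutant nerves at 7 days to 8.19 ± 0.776 CPM in wild type nerves at 3 days (SD, n = 3 each). A gene-level count covers reads from every exon, so it does not show a deletion of part of the gene.

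**Figure D1:**
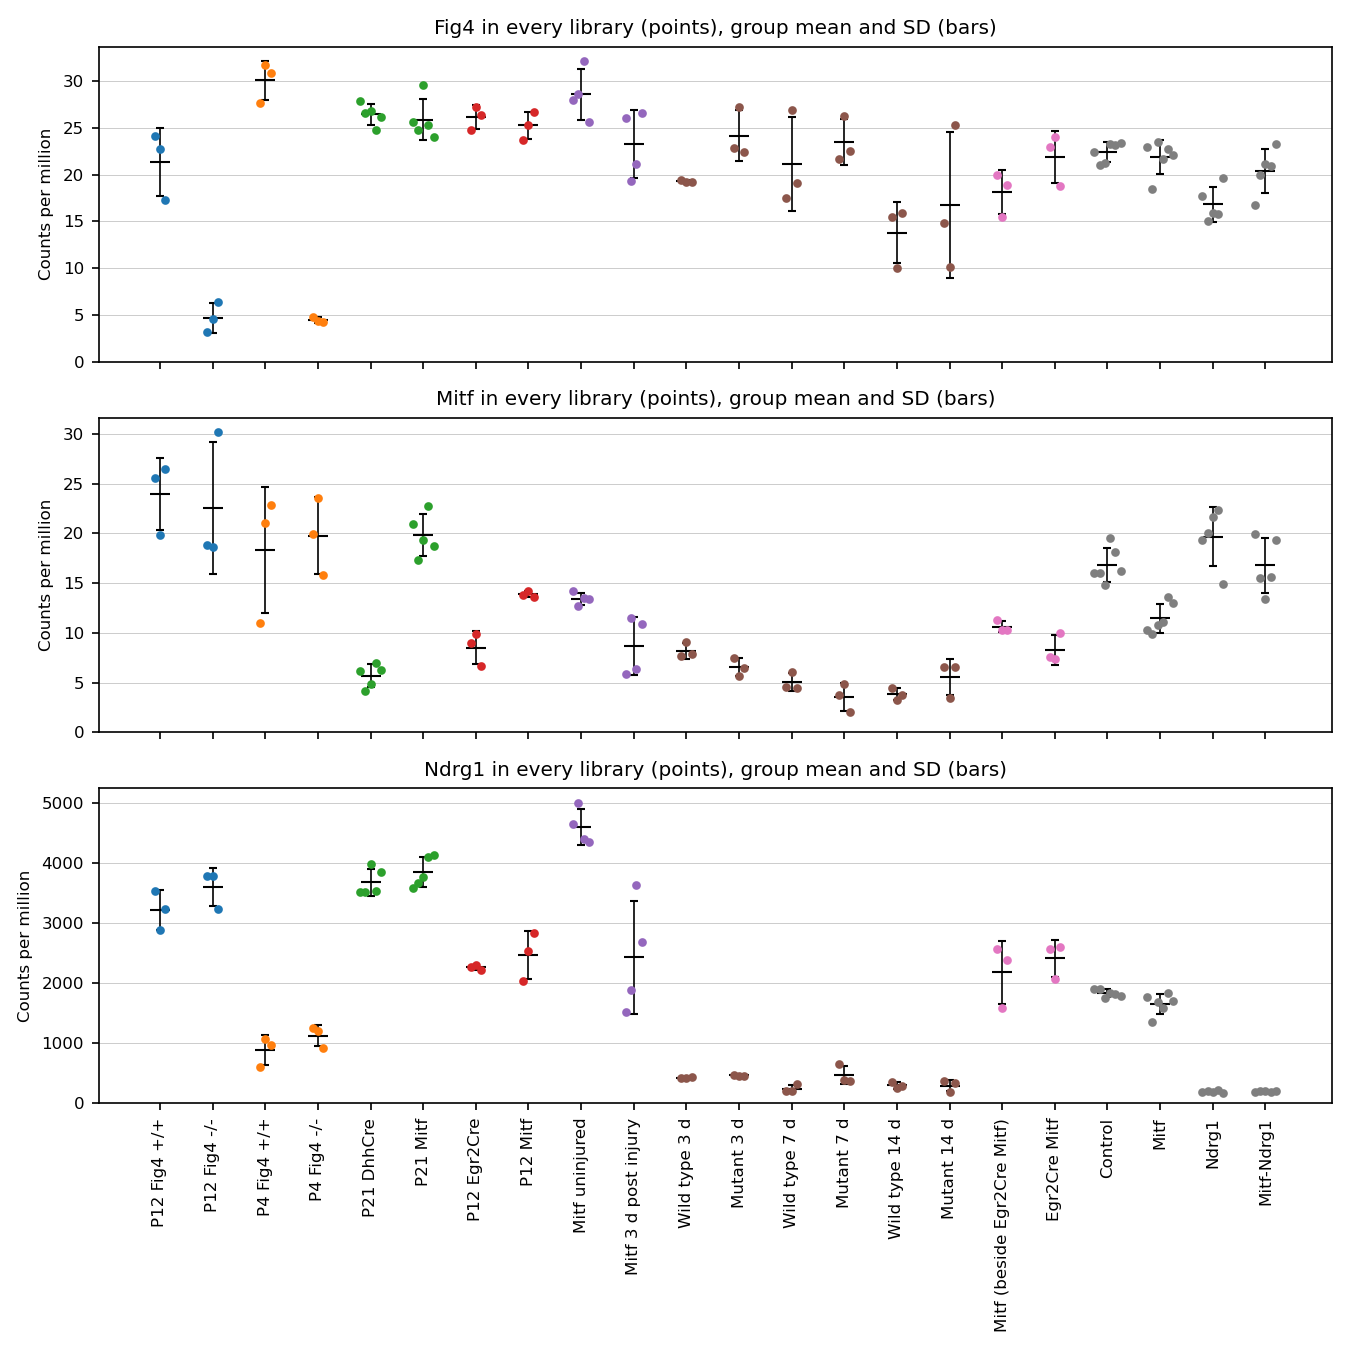
CPM (y axes) of Fig4, Mitf and Ndrg1 in each of the 82 libraries (points) of the 22 groups (x axis, colours mark the tables), with group means and SDs as bars. Fig4 lies near 4.7 CPM in Fig4 -/- nerves at P12, Mitf near 5.7 CPM in DhhCre libraries, and Ndrg1 near 192 CPM in Ndrg1 and 196 CPM in Mitf-Ndrg1 libraries.

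At P12, Fig4 -/- nerves differed from Fig4 +/+ nerves (n = 3 each) in a set of genes known from injured Schwann cells and in lipid synthesis. Jun, the transcription factor that starts the repair program of Schwann cells, was higher by 1.32 on the log2 scale (SE 0.191, edgeR adjusted p = 0.00348). Ngfr, the low-affinity neurotrophin receptor of immature and repair cells, rose by 2.48 (SE 0.198, adjusted p = 4.57e-05), and Atf3, a stress-induced transcription factor, rose by 2.71 (SE 0.186, adjusted p = 1.43e-05). Fig4 itself fell by 2.35 (SE 0.281, adjusted p = 0.00084). In all, 435 of 14338 tested genes passed, 268 higher and 167 lower, and 170 higher and 37 lower genes reached an absolute log2 change of 1.

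Of the higher genes, the smallest p belonged to Lgals3, a galectin that binds damaged lysosomes, at 5.23 (SE 0.193, adjusted p = 7.48e-08). Fgd3 rose by 3.98, Atp6v0d2, a subunit of the lysosomal proton pump, by 4.39, and Pmel, a pigment granule protein, by 5.17. Abca1, a cholesterol exporter, rose by 2.41, Cd44, a hyaluronan receptor, by 2.12, and Cxcl14, a chemokine, by 3.86. Among the lower genes were Acsl3, which activates fatty acids, at -1.09 (SE 0.138), Lss, an enzyme of cholesterol synthesis, at -1.27 (SE 0.171), and Tmem245 at -1.06. Adgb stood at -2.17 (SE 0.319), and Cntn1, an axonal and glial adhesion molecule, at -1.52 (SE 0.228).

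Of 29 measured genes of the repair Schwann cell list, 15 rose and none fell over all genes tested, and 21 rose adjusted over the list alone. They included Tnc, an injury-induced matrix protein (2.16, SE 0.198), Runx2 (3.37, SE 0.347), Btc, an epidermal growth factor relative (4.91, SE 0.517), and Gdnf, a trophic factor for neurons (6.40, SE 1.23). The list's median was 2.16 and camera called it higher (adjusted p = 1.34e-17; adjusted p = 0.12 with an estimated correlation). Of 11 non-myelinating Schwann cell genes, 4 rose, 6 adjusted over the list alone, among them Sox2 (1.51, SE 0.256) and Ngfr (camera adjusted p = 1.73e-05; adjusted p = 0.175 with an estimated correlation). Of 38 lysosome genes, 14 rose and none fell, 17 adjusted over the list alone. Gpnmb rose by 5.27 (SE 0.367), Cd63 by 1.35 (SE 0.113), the protease gene Ctsd by 1.23 (SE 0.137) and Ctsb by 0.94 (SE 0.138). Camera called this list higher (median 0.443, adjusted p = 4.26e-17), and the call held with an estimated correlation (adjusted p = 0.0258). Of 11 pigment cell genes 3 rose, namely Pmel, Tyrp1 (3.99, SE 0.312) and Met, a growth factor receptor (1.23, SE 0.143). That list's median was 1.12 (camera adjusted p = 6.77e-05; adjusted p = 0.12 with an estimated correlation), and 0.414 without Fig4 -/- replicate 2. Of 28 cell cycle genes 5 rose, 11 adjusted over the list alone, including Cdk1 (1.36, SE 0.265) and Bub1, a checkpoint kinase (2.02; camera adjusted p = 3.62e-09; adjusted p = 0.146 with an estimated correlation).

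Of 24 cholesterol synthesis genes 16 fell and none rose, and 22 fell adjusted over the list alone. Hmgcs1 (-1.11, SE 0.17) and Sc5d (-0.92) were among them. The median was -0.796 (camera adjusted p = 2.92e-22; adjusted p = 0.146 with an estimated correlation). Of 20 myelin genes 4 fell, namely Cldn19, a tight junction protein of myelin (-0.61, SE 0.125), Drp2 (-0.67, SE 0.14), Ugt8a, which makes myelin galactolipids (-0.72, SE 0.167), and Mbp, myelin basic protein (-0.69, SE 0.167, adjusted p = 0.0495). Adjusted over the list alone, 9 fell and 1 rose. The myelin median was -0.375 (camera adjusted p = 6.77e-05; adjusted p = 0.451 with an estimated correlation), and -0.233 without Fig4 +/+ replicate 1.

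Of 18 macrophage genes 9 rose, 10 adjusted over the list alone, including Lyz2, lysozyme (1.25, SE 0.12), Trem2, a lipid receptor of phagocytes (1.78, SE 0.274), and Cd68, a lysosomal protein of phagocytes (1.55, SE 0.269). Their median was 0.681 (camera adjusted p = 1.81e-07; adjusted p = 0.356 with an estimated correlation). Of 20 extracellular matrix genes 3 rose, 4 adjusted over the list alone: Timp1, a protease inhibitor (3.04, SE 0.503), Spp1, osteopontin (2.12), and Postn (0.73; camera adjusted p = 0.0262; adjusted p = 0.484 with an estimated correlation). Camera did not call that list without replicate 3 of either genotype (adjusted p = 0.212 and 0.309). Of 16 glycolysis genes 1 rose, Pfkp (0.97; camera adjusted p = 0.00373; adjusted p = 0.477 with an estimated correlation). Camera called neither the integrated stress response list (16 genes, none past the test, adjusted p = 0.564) nor the interferon response list (15 genes, none past the test, adjusted p = 0.358). The same held for immediate early and heat shock genes (10 genes, none past the test, adjusted p = 0.262), for the axon-induced growth factor and Neuregulin list (17 genes, 1 higher and 3 lower, adjusted p = 0.564) and for endothelial genes (12 genes, adjusted p = 0.262), of which Kdr, a vascular growth factor receptor, fell by 0.65 (SE 0.142). Of 12 fibroblast genes 1 fell, Dpt (-1.13; camera adjusted p = 0.0518). Of 5 erythrocyte genes 1 rose, the haemoglobin gene Hbb-bs (1.18; camera adjusted p = 0.00025; adjusted p = 0.34 with an estimated correlation). Skeletal muscle genes, 8 of which were measured, had a median of -2.68 (camera adjusted p = 0.00627; adjusted p = 0.484 with an estimated correlation). One of them passed the test, Tnnc2, and 5 fell adjusted over the list alone. None of the measured mast cell, pericyte and smooth muscle, perineurial or adipocyte genes passed the test.

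Gene sets from other tables moved in the same comparison. Of 751 measured genes that rose 3 days post injury in nerves labelled Mitf, 107 rose and none fell in Fig4 -/- nerves (median 0.554, camera adjusted p = 1.31e-24; adjusted p = 0.027 with an estimated correlation). Of 292 genes that fell after injury, 57 fell and 2 rose (median -0.458, camera adjusted p = 4e-24; adjusted p = 0.0424 with an estimated correlation). Of 1374 genes higher in Ndrg1 libraries, 138 rose and none fell (median 0.494, camera adjusted p = 5.23e-16; adjusted p = 0.0424 with an estimated correlation). Of 1149 genes lower in Ndrg1 libraries, 107 fell and 4 rose (median -0.324, camera adjusted p = 2.32e-16; adjusted p = 0.0749 with an estimated correlation). The number of called genes ran from 146 to 709 with single libraries left out. It was 922 with DESeq2 (473 higher and 449 lower), 1131 without the low-count filter (549 higher and 582 lower) and 29 with a skeletal muscle covariate chosen after seeing the data (26 higher and 3 lower).

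At P4, Fig4 was the 1 gene of 14888 that passed the test between Fig4 -/- and Fig4 +/+ nerves (-2.76, SE 0.139, edgeR adjusted p = 0.0133, n = 3 each). At an unadjusted p under 0.05 there were 126 genes (0.846%, below the share of 0.05 that chance alone gives), and DESeq2 called 8. Several genes higher at P12 had positive values at P4, each with an adjusted p of 1: Pmel (2.60, SE 0.49), Atp6v0d2 (2.41, SE 0.531), Gpnmb (2.39, SE 0.622), Tyrp1 (1.89, SE 0.267) and Jun (0.47). No list member passed the test over all genes, while 2 pigment cell genes, 2 neutrophil genes and 1 erythrocyte gene passed adjusted over the list alone. The lysosome list had a median of 0.122 (38 genes, camera adjusted p = 4.44e-07; adjusted p = 0.263 with an estimated correlation), and the repair list 0.137 (24 genes, camera adjusted p = 4.23e-05; adjusted p = 0.106 with an estimated correlation). Other lists and sets went against the P12 direction: cholesterol synthesis (0.0815, camera adjusted p = 0.0158) and myelin genes (0.0306, adjusted p = 0.0282; adjusted p = 0.74 with an estimated correlation for both) were called higher and cell cycle genes lower (-0.058, adjusted p = 0.00882; adjusted p = 0.426 with an estimated correlation). The sets that fell after injury (0.0664, adjusted p = 0.0227) and in Ndrg1 libraries (0.0576, adjusted p = 0.00392) were called higher (adjusted p = 0.978 with an estimated correlation for both). Without Fig4 +/+ replicate 1 the medians of cholesterol synthesis (-0.108) and myelin genes (-0.216) and of both sets (-0.151 and -0.138) turned to the P12 direction. Camera called further lists, higher for erythrocyte, neutrophil, pericyte and smooth muscle, immediate early and heat shock, pigment cell, extracellular matrix and axon-induced growth factor and Neuregulin genes (medians 0.0782 to 2.72, adjusted p = 8.86e-06 to 0.0423), and lower for adipocyte (-1.43, adjusted p = 0.000191) and perineurial genes (-0.199, adjusted p = 0.00186; lowest adjusted p = 0.106 with an estimated correlation). Without Fig4 +/+ replicate 1 neither the lysosome nor the repair list was called (adjusted p = 0.0766 for lysosome genes and 0.0604 for repair genes). Of the P12 set, 157 genes that rose had a median of 0.148 at P4, none of them called (camera adjusted p = 3.42e-16; adjusted p = 0.093 with an estimated correlation), and 0.0612 without Fig4 -/- replicate 3. The count was 0 without Fig4 -/- replicate 1 or 2 or without Fig4 +/+ replicate 2 or 3. Without Fig4 -/- replicate 3 Fig4 lost its call and 1 other gene passed as higher. The count was 13 without the muscle-rich libraries, which were chosen after seeing the data.

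The Fig4 effect was compared between the ages by an interaction. Of 13765 genes 23 passed, 21 more positive and 2 more negative at P12 (edgeR). Age cannot be told apart from table, and splits did not exclude chance. Fgd3 led (3.54, SE 0.304, adjusted p = 0.000452), followed by Hmga1, a chromatin protein of growing cells (3.53, SE 0.307), and Dclk1, a kinase that binds microtubules (1.83, SE 0.199). Cxcl14 (3.90, SE 0.467), Lgals3 (3.59, SE 0.482), Gpc1 (1.90, SE 0.251) and the macrophage gene Mpeg1 (2.42, SE 0.343) also passed. Of 29 repair genes 3 had a more positive effect at P12, namely Tnc (2.15, SE 0.362), Atf3 (1.87, SE 0.316) and Btc (SE 0.812), each with an adjusted p of 0.0494, and 14 did so adjusted over the list alone. The list's median difference was 1.87 (camera adjusted p = 6.1e-16; adjusted p = 0.0248 with an estimated correlation). Of 28 cell cycle genes 1 passed, Bub1 (2.06, SE 0.32), and 10 adjusted over the list alone (median 1.01, camera adjusted p = 6.1e-16; adjusted p = 0.0248 with an estimated correlation). Cholesterol synthesis genes had a median of -0.898 with none of 25 past the test and 5 lower adjusted over the list alone (camera adjusted p = 1.79e-14; adjusted p = 0.326 with an estimated correlation). Camera also called lysosome, macrophage, pigment cell, non-myelinating Schwann cell and glycolysis genes more positive (medians 0.326 to 1.10, adjusted p = 2.2e-08 to 0.0468) and myelin genes more negative (-0.397, adjusted p = 0.00314; lowest adjusted p = 0.131 with an estimated correlation). The injury set of 751 genes had a median of 0.619, with 15 more positive and none more negative (camera adjusted p = 2.09e-26; adjusted p = 0.0458 with an estimated correlation). The count ran from 5 to 26 with single libraries left out. It was 13 with RLE scaling and 148 with DESeq2, and, by choices made after seeing the data, 64 with a muscle covariate and 47 without the muscle-rich libraries.

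At P21, Mitf was the gene with the smallest p between libraries labelled Mitf and DhhCre (n = 5 each), at 1.77 (SE 0.124, edgeR adjusted p = 2.95e-05). The other of 2 genes past the test out of 13943 was Rpl36a-ps3 (5.79, SE 0.57, adjusted p = 0.000951). That pseudogene lies outside the rule for named genes, was named after its value was seen, and is uncertain because it shares reads with near-identical copies. Neither Fig4 nor Ndrg1 passed the test, with Ndrg1 at 3850 ± 251 CPM in Mitf and 3680 ± 223 CPM in DhhCre libraries (SD, n = 5 each). No other member of a fixed list passed. Cell cycle genes had a median of 0.235 (27 genes, camera adjusted p = 1.11e-05) and myelin genes one of -0.0846 (20 genes, camera adjusted p = 0.00268; adjusted p = 0.585 with an estimated correlation for both). Camera did not call the myelin list without DhhCre replicate 3 (adjusted p = 0.212) or Mitf replicate 4 (adjusted p = 0.0529). Camera also called macrophage (0.107, adjusted p = 0.00211), erythrocyte (0.396, adjusted p = 0.00237), endothelial (0.164, adjusted p = 0.00377) and fibroblast genes (0.199, adjusted p = 0.00599; adjusted p = 0.585 with an estimated correlation for each) as higher in Mitf libraries, and extracellular matrix (0.143, adjusted p = 0.00363) and cholesterol synthesis genes (0.0669, adjusted p = 0.0255; lowest adjusted p = 0.751 with an estimated correlation). Repair Schwann cell genes had a median of -0.0387 (20 genes, camera adjusted p = 0.767) and lysosome genes one of -0.0309 (camera adjusted p = 0.118). With the replicate number as a block 4 genes passed. DESeq2 called 12, and 408 genes had an unadjusted p under 0.05 (2.93%, fewer than chance alone gives).

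At P12, libraries labelled Mitf and Egr2Cre (n = 3 each) differed in 2 of 14415 genes, both lower in Mitf libraries and neither of them in a fixed list (edgeR). They were Rpl15-ps2 (-4.84, SE 0.396) and Gm5292 (-6.41, SE 0.533), each with an adjusted p of 0.0227, named after their values were seen; copies of ribosomal protein genes share reads, so Rpl15-ps2 is uncertain. Mitf stood at 0.73 (SE 0.151, adjusted p = 1). No list member passed the test. Macrophage genes had a median of 0.424 (0.281 to 0.696 with single libraries left out; camera adjusted p = 6.43e-13) and cell cycle genes one of 0.232 (28 genes, camera adjusted p = 2.69e-08; adjusted p = 0.725 with an estimated correlation for both). Adipocyte (1.08, camera adjusted p = 5.18e-05) and erythrocyte genes (1.15, adjusted p = 0.00107) were called higher, and mast cell (-0.483, adjusted p = 0.00982), cholesterol synthesis (-0.0803, adjusted p = 0.00616), glycolysis (-0.23, adjusted p = 0.0274) and endothelial genes (-0.146, adjusted p = 0.0353) lower (adjusted p = 0.725 with an estimated correlation for each). Skeletal muscle genes had a median of -7.39 (camera adjusted p = 0.00344; adjusted p = 0.725 with an estimated correlation), with a score (mean log2 CPM of the list) of 9.11 in Egr2Cre replicate 3. No gene passed without Mitf replicate 1 or 3, without Egr2Cre replicate 3 or with a sex covariate; DESeq2 called 9, 4 passed without the low-count filter, and 371 had an unadjusted p under 0.05.

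In the table without an age, no gene of 15482 passed edgeR's test between libraries labelled Egr2Cre Mitf and Mitf (n = 3 each; smallest adjusted p = 0.846). DESeq2 called 7, and 671 genes had an unadjusted p under 0.05. Mitf stood at -0.45 (SE 0.172). Of the lists without a member past the test, the repair list had a median of 0.357 (30 genes, camera adjusted p = 2.94e-08) and the lysosome list one of 0.181 (38 genes, camera adjusted p = 3.84e-06; adjusted p = 0.443 with an estimated correlation for both). Non-myelinating Schwann cell genes had a median of 0.412 (camera adjusted p = 8.64e-07) and axon-induced growth factor and Neuregulin genes one of 0.212 (adjusted p = 0.00993; adjusted p = 0.443 with an estimated correlation for both). Macrophage (0.248, camera adjusted p = 6.74e-05), cell cycle, extracellular matrix, adipocyte and erythrocyte genes were called higher along with them (medians 0.217 to 1.56, adjusted p = 6.5e-05 to 0.0297), and mast cell genes lower (-0.487, adjusted p = 0.00337; adjusted p = 0.682 with an estimated correlation for each). Skeletal muscle genes had a median of -0.759 in the same comparison (camera adjusted p = 0.011; adjusted p = 0.682 with an estimated correlation).

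At 3 days post injury, nerves labelled Mitf differed from uninjured nerves labelled Mitf (n = 4 each) in 3365 of 15245 genes, 1785 higher and 1580 lower (edgeR). Timp1, a protease inhibitor, rose by 5.61 on the log2 scale (SE 0.162, adjusted p = 8.98e-08). Clcf1, a neurotrophic cytokine, rose by 5.37 (SE 0.276, adjusted p = 1.94e-05). Lss fell by 1.50 (SE 0.146, adjusted p = 0.00103). Ndrg1 fell by 0.94 (SE 0.26, adjusted p = 0.0275), while Mitf stood at -0.64 (SE 0.261, adjusted p = 0.107). An absolute log2 change of 1 was reached by 837 higher and 304 lower genes.

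Other leading genes were Tnfrsf12a, a receptor of the tumour necrosis factor family (3.43, SE 0.218), Syt4, a synaptotagmin (2.97), Cd44 (2.61, SE 0.211), Wif1, a Wnt inhibitor (SE 0.445), and Plekho1. On the lower side were Dixdc1 (-1.59), Aacs, which feeds ketone bodies into lipid synthesis (-1.12, SE 0.126), Zfp871 (-1.57), Kdm1b (-1.08), Bicd1 (-1.58), Mturn and Rspo1. Of 28 repair genes 18 rose and 1 fell, 21 and 2 adjusted over the list alone. They included Shh, a morphogen of repair cells (4.76, SE 0.402), Gdnf (7.30, SE 0.9), Jun (1.33, SE 0.169, adjusted p = 0.002) and Ngfr (2.03, SE 0.283). The list's median was 2.29 (camera adjusted p = 2.41e-08; adjusted p = 0.468 with an estimated correlation, a value that holds for each fixed list that camera called here). Of 27 cell cycle genes 24 rose, and all 27 adjusted over the list alone, including E2f1 (2.75, SE 0.258) and Cdk1 (4.44, SE 0.535; median 2.79, camera adjusted p = 5.01e-13). Of 25 cholesterol synthesis genes 20 fell and none rose, 22 adjusted over the list alone, including Idi1 (-1.13) and Stard4 (-0.97; median -0.974, camera adjusted p = 5.01e-13).

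Of 20 myelin genes 9 fell and 1 rose, 14 and 1 adjusted over the list alone (median -0.898, camera adjusted p = 1.55e-05). Mbp fell by 1.14 (SE 0.279, adjusted p = 0.0178), Drp2 by 1.29 and the gap junction gene Gjc3 by 0.70, whereas Gjb1, another gap junction gene, rose by 0.83 (SE 0.143, adjusted p = 0.00492). Of 19 macrophage genes 7 rose, 12 adjusted over the list alone, including Aif1 (1.69, SE 0.2), Ccr2, a receptor of recruited monocytes (1.91), and Arg1 (SE 1.1; median 0.96, camera adjusted p = 3.97e-05). Of 38 lysosome genes 11 rose and 2 fell, among the former Atp6v0d2 (4.00, SE 0.446) and Cd63 (1.05; median 0.141, camera adjusted p = 0.0485). Camera did not call the lysosome list with a sex covariate (adjusted p = 0.0505). Of 9 perineurial genes 3 fell, including Itgb4, a basement membrane receptor (-1.21), and Ntng1 (-1.15; median -1.06, camera adjusted p = 0.002). Mast cell (-1.14, camera adjusted p = 0.0331) and erythrocyte genes (-1.13, 1 gene lower, adjusted p = 0.0337) were called lower too. Of 16 glycolysis genes 4 rose and 1 fell, 6 and 1 adjusted over the list alone (median 0.473, camera adjusted p = 0.0227; not called without injured replicate 1, adjusted p = 0.0573).

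Sets from other tables moved with injury. Of 163 genes higher in Fig4 -/- nerves at P12, 102 rose and 3 fell after injury (median 1.33, camera adjusted p = 3.12e-26), and of 36 lower genes 16 fell and none rose (median -0.632, camera adjusted p = 1.86e-09). Of 1626 genes higher in Ndrg1 libraries, 705 rose and 2 fell (median 1.23, camera adjusted p = 4.56e-33), and of 1186 lower genes 493 fell and 2 rose (median -0.736, camera adjusted p = 1.37e-33). These calls held with an estimated correlation (adjusted p = 0.035 each). The skeletal muscle list had a median of -5.33 with none of 9 past the test over all genes and 9 lower adjusted over the list alone (camera adjusted p = 0.166); their scores in uninjured replicates 1 to 4 were 3.58, -0.00736, -0.82 and 6.45. The count ran from 1816 to 4058 with single libraries left out, and was 1068 with the muscle covariate chosen after seeing the data.

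In wild type nerves, repair, cell cycle and lysosome genes were lower at 14 than at 3 days post injury. Fibroblast, perineurial and muscle genes were higher. Of 15852 genes 9056 passed, 4578 higher and 4478 lower (edgeR, n = 3 each). Plaur, the urokinase receptor, fell by 3.36 (SE 0.162, adjusted p = 1.33e-08). Clcf1 fell by 7.32 (SE 0.452), Shh by 8.14 and Spp1 by 3.96 (SE 0.266). Meox2, a homeobox gene, rose by 2.77 (SE 0.164, adjusted p = 4.08e-08), Omd, a small proteoglycan, by 3.74 (SE 0.229), Cldn1, the perineurial claudin, by 3.94 (SE 0.243) and Itm2a by 4.26 (SE 0.263). Ccdc117 (1.65, SE 0.0997), Lgals7 (4.30, SE 0.269), Sspn and Dapk2 also rose, and Me2 (-2.04, SE 0.103), Fam102a (-5.44, SE 0.276), Ggct (-2.41, SE 0.135), Tmem150a (-1.89), Acot7 (-2.43), Bcl2l1 (-2.10) and Gclm, of glutathione synthesis (-1.73), also fell. Mitf fell by 0.66 (SE 0.244, adjusted p = 0.0308).

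Of 32 repair genes 22 fell and 4 rose, 23 and 4 adjusted over the list alone (median -1.71, camera adjusted p = 4.25e-05; adjusted p = 0.575 with an estimated correlation). Fosl1 fell by 5.74 (SE 0.385), Gdnf by 5.84 and Ngfr by 3.02, while Olig1 (4.98, SE 0.442) and Gap43, a growth cone protein (2.41, SE 0.235), rose. Of 28 cell cycle genes 26 fell, the same number adjusted over the list alone, for example Mki67 (-2.76) and E2f1 (-1.96; median -1.57, camera adjusted p = 9.91e-11; adjusted p = 0.561 with an estimated correlation). Of 38 lysosome genes 25 fell and 5 rose, the same numbers adjusted over the list alone, with Gla at -2.36 (median -0.769, camera adjusted p = 0.000263; adjusted p = 0.584 with an estimated correlation). Of 12 fibroblast genes 10 rose, including Dcn, decorin (1.98, SE 0.197), and 10 rose and 1 fell adjusted over the list alone (median 1.45, camera adjusted p = 0.00114; adjusted p = 0.561 with an estimated correlation). Of 20 extracellular matrix genes 5 rose and 5 fell (camera adjusted p = 0.979), and of 19 macrophage genes 2 rose and 8 fell (camera adjusted p = 0.0313; adjusted p = 0.804 with an estimated correlation). Of 9 perineurial genes 7 rose and 1 fell (median 1.48, camera adjusted p = 0.00438; adjusted p = 0.561 with an estimated correlation), and each of 8 lymphocyte genes rose, Cd3d by 3.73 and Trac by 2.43 (median 2.48, camera adjusted p = 0.00438; adjusted p = 0.501 with an estimated correlation). Of 20 myelin genes 6 fell, Gjb1 by 8.53 (SE 0.506), and 1 rose (camera adjusted p = 0.169). Each of 13 skeletal muscle genes rose (median 6.08, camera adjusted p = 0.000259; adjusted p = 0.575 with an estimated correlation), with scores of 3.93, 6.19 and 5.31 at 3 days and 8.82, 12.4 and 12.1 at 14 days. Of 836 genes that rose in the separate injury table, 508 fell and 79 rose by 14 days (median -0.878, camera adjusted p = 1.48e-14; adjusted p = 0.0462 with an estimated correlation). With the muscle covariate chosen after seeing the data 4177 genes passed, but time and muscle RNA ran together.

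Mutant and wild type nerves were compared at each time after injury (n = 3 each). At 3 days no gene of 15852 passed edgeR's test, DESeq2 called 0, and 299 genes had an unadjusted p under 0.05; Mitf stood at -0.36 (SE 0.239). Repair genes (median 0.118, camera adjusted p = 0.596), myelin genes (camera adjusted p = 0.827) and lysosome genes (camera adjusted p = 0.827) were not called. Skeletal muscle genes had a median of -3.26 with no member past the test (13 genes, camera adjusted p = 7.56e-21; adjusted p = 0.156 with an estimated correlation), and -5.13 without Mutant replicate 1. Camera also called endothelial (-0.235, adjusted p = 0.000271), erythrocyte (-0.94, adjusted p = 0.000406), neutrophil (-1.23, adjusted p = 0.00551), interferon response (-0.299, adjusted p = 0.0292) and adipocyte genes (-0.346, adjusted p = 0.0323) lower (lowest adjusted p = 0.671 with an estimated correlation).

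At 7 days no gene passed edgeR's test either (smallest adjusted p = 0.0554, for Nat8l), while 2094 genes (13.2%) had an unadjusted p under 0.05 and DESeq2 called 242. Of 20 myelin genes none passed over all genes and 16 were higher in Mutant nerves adjusted over the list alone, with Gjb1 at 2.02 (SE 0.39, adjusted p = 0.13). The list's median was 2.20 (camera adjusted p = 1.07e-06; adjusted p = 0.396 with an estimated correlation). It was 0.361 without Mutant replicate 1, whose myelin score was 7.32 against 4.43 and 4.10 in the other Mutant and 3.78 to 4.12 in the wild type libraries. Camera also called the repair list (0.361, adjusted p = 8.53e-05; adjusted p = 0.411 with an estimated correlation), and the non-myelinating (0.646, adjusted p = 1.71e-05), adipocyte (0.78, adjusted p = 1.72e-05) and perineurial lists (0.502, adjusted p = 0.0016; adjusted p = 0.308 with an estimated correlation for each) as higher. Ndrg1 stood at 0.88 (SE 0.223, adjusted p = 0.185). Endothelial genes had a median of 0.575 (camera adjusted p = 1.07e-06; adjusted p = 0.308 with an estimated correlation) and macrophage genes one of -0.332 (-0.807 to -0.155 with single libraries left out; camera adjusted p = 1.72e-05; adjusted p = 0.394 with an estimated correlation). For skeletal muscle genes the median was -2.86 (camera adjusted p = 2.11e-05; adjusted p = 0.404 with an estimated correlation). The count ran from 0 to 11 with single libraries left out, and was 2 with RLE scaling and 3 without the low-count filter.

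At 14 days 1314 genes passed, 1117 higher and 197 lower in Mutant nerves (edgeR). Meg3, a long non-coding RNA kept in the nucleus, was higher by 2.72 (SE 0.289, adjusted p = 0.00113), Uaca by 1.19 (SE 0.131), Cdc42bpg, a kinase of the cytoskeleton, by 1.41 (SE 0.177), Eea1, an early endosome protein, by 1.38 (SE 0.175), Leng8 by 1.88 (SE 0.239), Fam193b by 1.58 (SE 0.209) and Dzip1 by 1.46 (SE 0.195). Inpp4a, a phosphoinositide phosphatase, also rose (SE 0.194). Lower genes were led by Ctgf, a matrix-associated growth factor (-1.15, SE 0.187, adjusted p = 0.00404), Myh2, a muscle myosin (-2.96, SE 0.487), Tmem252 (-1.09, SE 0.209), Opn3 (-1.26), Tmem45b (-1.77), Mmd (-1.02), Tnnt1, a muscle troponin (-4.44, SE 1.01), and Ifi27l2a (-2.01, SE 0.475). Of 28 cell cycle genes 3 rose, Mki67 (1.66, SE 0.289), Cenpe (1.63, SE 0.318) and Cenpf (1.11, SE 0.245), also 3 adjusted over the list alone (camera adjusted p = 0.105). Of 8 neutrophil genes 2 rose, Mpo (5.18, SE 1.19) and Camp (3.83, SE 0.884), and 5 adjusted over the list alone (camera adjusted p = 0.397). Of 14 adipocyte genes 1 fell, Cfd (-1.58, SE 0.423), and 4 adjusted over the list alone (median -0.924, camera adjusted p = 0.000125; adjusted p = 0.991 with an estimated correlation; median -1.45 without Mutant replicate 1).

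No myelin gene (20 genes, camera adjusted p = 0.964), repair gene (32 genes, camera adjusted p = 0.964), lysosome gene (camera adjusted p = 0.624) or macrophage gene (camera adjusted p = 0.982) passed at 14 days. Skeletal muscle genes had a median of -0.444 (camera adjusted p = 0.437), with scores of 9.94, 12.3 and 8.51 in Mutant and 8.82, 12.4 and 12.1 in wild type replicates 1 to 3. Mitf stood at 0.26 (SE 0.246, adjusted p = 0.505). Over the 3 times, genotype by time passed for 13 genes (edgeR), but chance was not excluded. Among them were Meg3 (adjusted p = 0.00103), Inpp4a and Tmem252 (adjusted p = 0.0334 each), Leng8 and the nuclear RNA Neat1 (adjusted p = 0.0454 each). The 14 day count depended on the libraries in the fit. It ran from 139 without wild type replicate 3 to 4959 (2642 higher and 2317 lower) without Mutant replicate 2, and was 0 when these 6 libraries were fitted alone. DESeq2 called 2312, and 846 passed without the low-count filter. The count of 13 ran from 1 to 146 with single libraries left out and was 410 with DESeq2 and 360 with the muscle covariate chosen after seeing the data.

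Ndrg1 libraries differed from controls (5 against 6) in 9626 of 15910 genes, 4896 higher and 4730 lower (edgeR). Among the leading higher genes were Ctss, a phagocyte protease (4.12, SE 0.113, adjusted p = 7.4e-19), and Gpnmb (5.45, SE 0.157, adjusted p = 1.78e-18). Myelin and cholesterol synthesis genes fell, with Fdft1, squalene synthase, at -1.88 (SE 0.0938). Ndrg1 itself fell by 3.44 (SE 0.0897, adjusted p = 3.57e-19). Mitf stood at 0.05 (adjusted p = 0.753), and Fig4 fell by 0.59 (SE 0.0917, adjusted p = 4.86e-06). An absolute log2 change of 1 was reached by 1918 higher and 1246 lower genes.

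Other genes named by rule were Ms4a7, a macrophage membrane protein (5.18, SE 0.15), Timp1 (5.34, SE 0.162), Lgmn, a lysosomal protease (2.23, SE 0.0681), Cd84 (3.90, SE 0.122) and Mpeg1, a pore-forming protein of phagocytes (4.58, SE 0.146) on the higher side. Lower were Aldoc, an enzyme of glycolysis (-2.82, SE 0.108), Acat2 (-2.03, SE 0.0979), Spon2 (-2.15, SE 0.106), Fez1 (-1.41, SE 0.0731), Mgl2 (-2.60, SE 0.138) and Lctl (-2.14, SE 0.114). Each of 20 myelin genes fell, for example Ugt8a (-2.09, SE 0.123), Mal (-1.72) and Pmp22 (-1.51; median -1.40, camera adjusted p = 1.81e-11; adjusted p = 0.0713 with an estimated correlation). Each of 25 cholesterol synthesis genes fell, including Insig1 (-2.08; median -1.90, camera adjusted p = 6.09e-18; adjusted p = 0.0656 with an estimated correlation). Of 31 repair genes 25 rose and 3 fell, among the former Clcf1 (3.88, SE 0.179), Btc (4.72, SE 0.241), Runx2 (3.13) and Gdnf (6.17, SE 0.422; median 2.66, camera adjusted p = 1.89e-09; adjusted p = 0.0656 with an estimated correlation). Of 28 cell cycle genes 27 rose, 28 adjusted over the list alone, including Birc5 (3.18, SE 0.138) and Cdk1 (3.40, SE 0.157; median 2.07, camera adjusted p = 3.17e-15; adjusted p = 0.0656 with an estimated correlation).

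Of 19 macrophage genes 17 rose and 1 fell, including Adgre1, a macrophage adhesion receptor (2.29, SE 0.0781), Lyz2 (3.91, SE 0.143) and Trem2 (3.88, SE 0.176; median 2.14, camera adjusted p = 1.81e-11). This call held with an estimated correlation (adjusted p = 0.0453). Each of 6 lymphocyte genes rose, Cd4 by 5.09 and Gzma by 4.45 (camera adjusted p = 0.015; adjusted p = 0.0656 with an estimated correlation). Of 12 endothelial genes 11 fell, including Kdr (-1.24, SE 0.109), Vwf (-1.41, SE 0.135) and Cdh5 (-0.92; median -0.822, camera adjusted p = 2.89e-05; adjusted p = 0.0656 with an estimated correlation). Of 38 lysosome genes 15 rose, among them Ctsb (1.70), Ctsd (1.93) and Atp6v0d2 (5.24), and 14 fell. Their median was -0.0171, while camera pointed upward without calling the list (adjusted p = 0.567). Of 9 perineurial genes 5 fell (camera adjusted p = 0.276), of 20 extracellular matrix genes 7 rose and 10 fell (camera adjusted p = 0.954), and of 16 glycolysis genes 3 rose and 3 fell (camera adjusted p = 0.954). No skeletal muscle gene passed (camera adjusted p = 0.917). Of 830 genes that rose in the injury table, 752 rose and 10 fell (median 1.48, camera adjusted p = 2.01e-52; adjusted p = 6.13e-06 with an estimated correlation), and of 300 that fell, 268 fell and 1 rose (median -1.30, camera adjusted p = 8.1e-38; adjusted p = 0.00778 with an estimated correlation). Of 169 genes higher in Fig4 -/- nerves, 138 rose and 10 fell (median 1.64, camera adjusted p = 8.9e-30; adjusted p = 1.54e-06 with an estimated correlation), and of 36 lower genes 30 fell and none rose (median -1.36, camera adjusted p = 1.39e-12; adjusted p = 0.00778 with an estimated correlation).

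**Figure D2:**
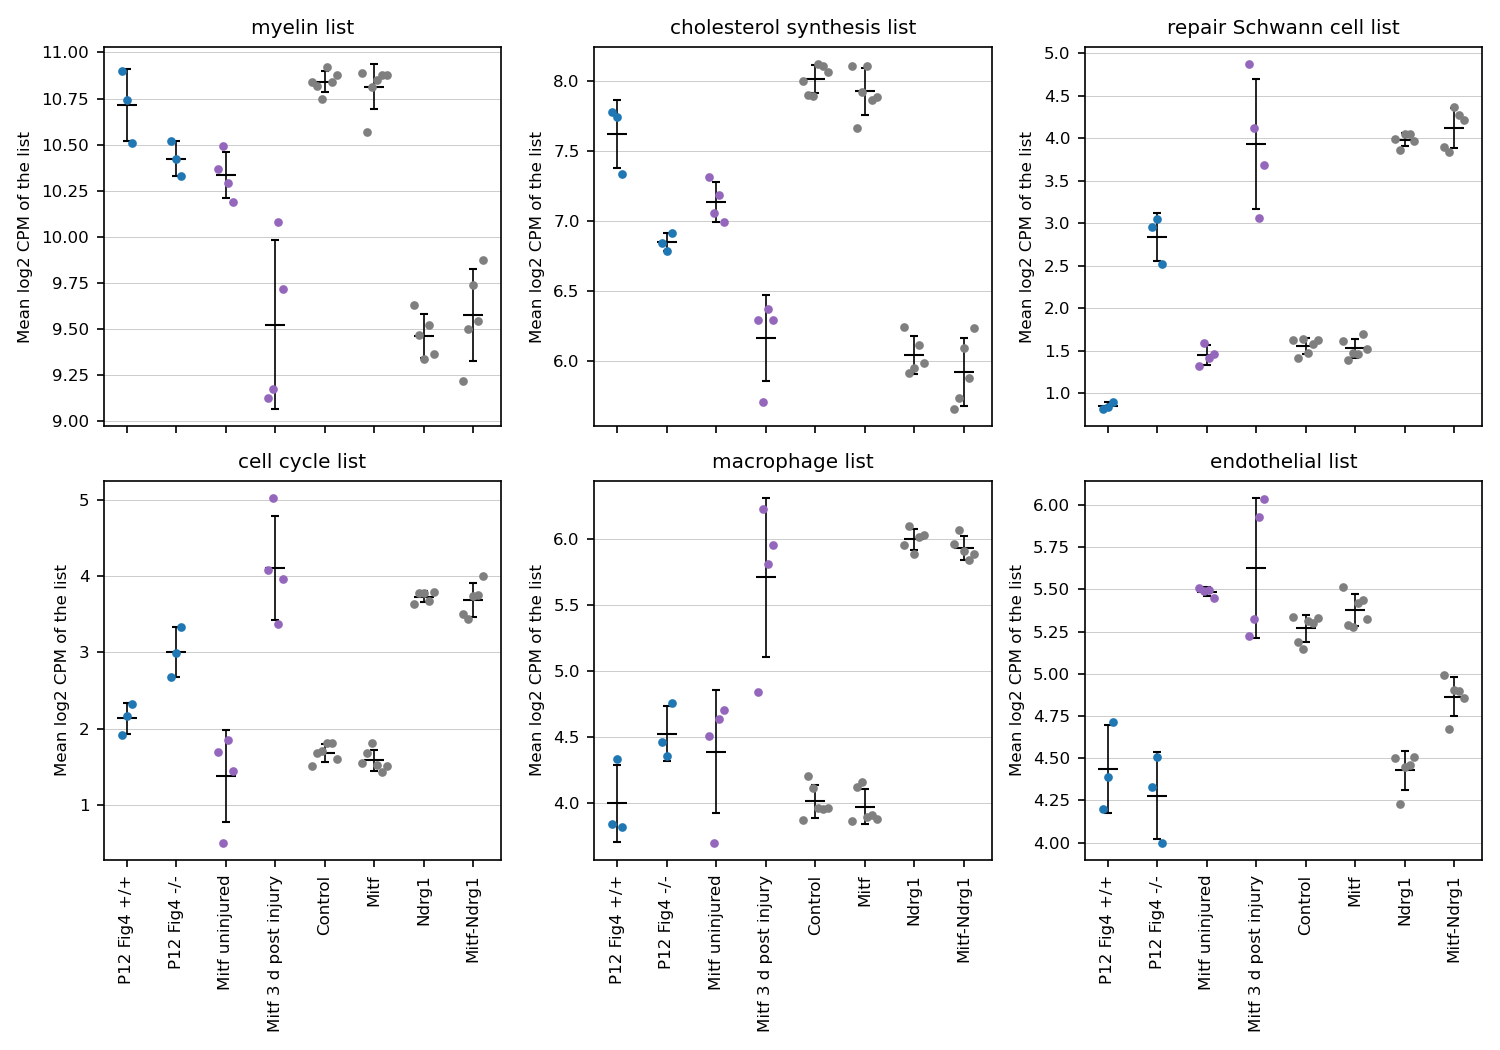
Mean log2 CPM (y axes) of 6 gene lists in each library (points) of 8 groups (x axis), with group means and SDs as bars; axes do not start at 0. Cholesterol synthesis lies between 5.91 and 6.24 in Ndrg1 and between 7.89 and 8.12 in control libraries, and the endothelial list between 4.23 and 4.51 in Ndrg1 and between 4.68 and 4.99 in Mitf-Ndrg1 libraries.

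Libraries labelled Mitf differed from controls (n = 6 each) in 1 gene of 15910, Alox5, which makes leukotrienes and fell by 0.95 (SE 0.14, edgeR adjusted p = 0.00832). Mitf stood at -0.55 (SE 0.118, adjusted p = 0.236). DESeq2 called 14, and 994 genes had an unadjusted p under 0.05. No list member passed. Lysosome genes had a median of -0.0681 (38 genes, camera adjusted p = 0.0108) and cholesterol synthesis genes one of -0.0952 (25 genes, camera adjusted p = 0.0118; adjusted p = 0.783 with an estimated correlation for both). Endothelial genes had a median of 0.144 (camera adjusted p = 0.0106; adjusted p = 0.783 with an estimated correlation). Without Mitf replicate 2 camera called neither the lysosome nor the cholesterol list (adjusted p = 0.175 and 0.36), and that library held the highest skeletal muscle score of the table (10.7). The muscle list had a median of 4.08 (camera adjusted p = 0.004; adjusted p = 0.783 with an estimated correlation). Of the count of 1 gene, none was left with a sex covariate, and 3 passed when these groups were fitted alone or without Mitf replicate 5 or 6.

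Mitf-Ndrg1 libraries differed from controls (5 against 6) in 9401 genes, 4863 higher and 4538 lower (edgeR). Ctss rose by 4.11, Ms4a7 by 5.50 (SE 0.152), Gpnmb by 5.40 and Timp1 by 5.43 (SE 0.162), and Aldoc fell by 3.29 (SE 0.111), Fdft1 by 2.09, Msmo1 by 1.82 and Insig1 by 2.21. Each of 20 myelin genes fell (median -1.32, camera adjusted p = 2.71e-11; adjusted p = 0.0861 with an estimated correlation), as did each of 25 cholesterol synthesis genes (median -2.06, camera adjusted p = 2.57e-20; adjusted p = 0.0567 with an estimated correlation). Of 31 repair genes 26 rose and 2 fell (median 2.64, camera adjusted p = 3.24e-11; adjusted p = 0.0547 with an estimated correlation). Of 19 macrophage genes 17 rose and 1 fell (median 2.01, camera adjusted p = 3.12e-11; adjusted p = 0.0488 with an estimated correlation). Of 28 cell cycle genes 27 rose (camera adjusted p = 1.85e-15; adjusted p = 0.0547 with an estimated correlation), as did 5 of 6 lymphocyte genes (camera adjusted p = 0.0481; adjusted p = 0.0861 with an estimated correlation). Of 12 endothelial genes 6 fell (camera adjusted p = 0.0644). Of 12 adipocyte genes 10 rose (median 2.44, camera adjusted p = 0.0774), but none did without the muscle-rich libraries (median 0.142), a choice made after seeing the data. The skeletal muscle median was 3.65 with no member past the test (camera adjusted p = 0.68). Fig4 fell by 0.38 (SE 0.0907, adjusted p = 0.000875), and Mitf stood at -0.25 (SE 0.123, adjusted p = 0.0863).

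Whether the Ndrg1 response was the same in Mitf-Ndrg1 libraries was read from genes chosen on other libraries. On odd-numbered control and Ndrg1 libraries, 2689 genes passed with an absolute log2 change of at least 1, 1574 higher and 1115 lower. Over these genes, signed by direction, held-out Ndrg1 libraries lay 1.67 above held-out controls (2 against 3, exact permutation p = 0.1, two-sided and the smallest this design can give). Mitf-Ndrg1 libraries lay 1.54 above the same controls (5 against 3, exact permutation p = 0.0179, also the smallest possible). The difference between Mitf-Ndrg1 and held-out Ndrg1 libraries was -0.128 (exact permutation p = 0.238), and that between Mitf and control libraries 0.0407 (exact permutation p = 0.512). With genes chosen on even-numbered libraries (2998 genes) these differences were -0.0856 (exact permutation p = 0.393) and 0.028 (exact permutation p = 0.69). Leaving out the 3 muscle-rich Mitf-Ndrg1 libraries, a choice made after seeing the data, gave -0.221 for the first.

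Compared directly, Mitf-Ndrg1 and Ndrg1 libraries (n = 5 each) differed in 234 genes, 170 higher and 64 lower in Mitf-Ndrg1 (edgeR). Markers of vessels and of the perineurial sheath made up a group among the higher genes. Pecam1, an endothelial adhesion molecule, rose by 0.87 (SE 0.121, adjusted p = 0.00082), and Cdh5, the endothelial cadherin, by 0.73 (SE 0.0991, adjusted p = 0.00082). Slc2a1, the glucose transporter of nerve barriers, rose by 0.58 (SE 0.108, adjusted p = 0.0101). Clu, a secreted chaperone, had the smallest p (1.04, SE 0.122, adjusted p = 0.00018), and Ccnd2, a cyclin, led the lower genes (-0.50, SE 0.0751, adjusted p = 0.00213). Also higher were Bmp3 (1.20, SE 0.213), Npy1r, a neuropeptide Y receptor (1.39, SE 0.252), Rims4 (1.73, SE 0.336), Egfl6 (1.11, SE 0.221), C1qtnf9 (1.06, SE 0.216), Kcna1, a potassium channel (1.14, SE 0.224), and Clec1a (1.04, SE 0.213). Cfap100 (-0.63, SE 0.116), Sec14l5 (-0.56, SE 0.103), Gprasp1 (-0.41), Bcat1 (-0.70, SE 0.136), Rimklb (-0.50), Taf15 (-0.38) and Akap8 (-0.40) were lower.

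Of 12 endothelial genes 7 rose, 8 adjusted over the list alone (median 0.471, camera adjusted p = 2.15e-10; adjusted p = 0.019 with an estimated correlation). Of 9 perineurial genes 5 rose, 8 adjusted over the list alone, among them Krt19 (1.27, SE 0.265) and Cldn1 (0.79, SE 0.175; median 0.786, camera adjusted p = 1.05e-08; adjusted p = 0.037 with an estimated correlation). Of 12 adipocyte genes 1 rose, Pnpla2 (0.83, SE 0.191), and 12 adjusted over the list alone (median 1.91, camera adjusted p = 1.77e-06; adjusted p = 0.435 with an estimated correlation). The adipocyte median was 0.0951 without the muscle-rich libraries. Pericyte and smooth muscle genes (median 0.378, camera adjusted p = 0.00056) and fibroblast genes (median 0.296, camera adjusted p = 0.00297) had no member past the test (adjusted p = 0.0656 with an estimated correlation for both), and camera called neither without the muscle-rich libraries (adjusted p = 0.134 and 0.109). Camera also called erythrocyte (1.03, adjusted p = 0.0217), glycolysis (0.426, 1 gene past the test, adjusted p = 0.00078), extracellular matrix, non-myelinating Schwann cell, lysosome, repair, interferon response and immediate early and heat shock genes higher (medians of the last 6 lists 0.085 to 0.216, adjusted p = 0.000399 to 0.0336) and cholesterol synthesis genes lower (-0.114, adjusted p = 0.00527; lowest adjusted p = 0.435 with an estimated correlation). No gene of the myelin list (median 0.111, camera adjusted p = 0.0336; adjusted p = 0.536 with an estimated correlation), of the macrophage list (median -0.0418, camera adjusted p = 0.106) or of the cell cycle list (median -0.0919, camera adjusted p = 0.11) passed. Skeletal muscle genes had a median of 4.14 (camera adjusted p = 0.0336; adjusted p = 0.569 with an estimated correlation), with scores of 7.91, 7.89 and 9.78 in Mitf-Ndrg1 replicates 1, 2 and 4. The count ran from 58 to 545 with single libraries left out. It was 31 when these groups were fitted alone, 750 with DESeq2, 141 with the muscle covariate and 587 without the muscle-rich libraries.

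The interaction of both labels asked whether the Mitf label had another effect with the Ndrg1 label than without it. It passed for 62 genes, 46 more positive and 16 more negative (74.2% positive; with RLE scaling 47 and 30, or 61% positive). Clu led (1.31, SE 0.165, edgeR adjusted p = 0.000579), followed by Fxyd6 (1.18, SE 0.199) and Irs3 (1.20, SE 0.203), and Spp1 passed at 2.15 (SE 0.383). Galnt9 (SE 0.717), Bmp3 (1.45, SE 0.285) and the perineurial genes Moxd1 (1.49, SE 0.293) and Krt19 (1.62, SE 0.357) were more positive, while Sec14l5 (-0.75, SE 0.139), Cdc7, a replication kinase (-0.99, SE 0.195), and Ccnd2 (-0.49, SE 0.102) were more negative. Of 9 perineurial genes 2 passed, 6 adjusted over the list alone (median 0.811, camera adjusted p = 2.1e-07; adjusted p = 0.119 with an estimated correlation). Of 12 endothelial genes none passed and 4 did adjusted over the list alone (median 0.384, camera adjusted p = 2.8e-05; adjusted p = 0.146 with an estimated correlation). Camera also called adipocyte, extracellular matrix, lysosome, non-myelinating Schwann cell, immediate early and heat shock, fibroblast, pericyte and smooth muscle and interferon response genes more positive (medians 0.0726 to 1.84, adjusted p = 0.000226 to 0.047; lowest adjusted p = 0.269 with an estimated correlation). The count ran from 20 to 252 with single libraries left out. DESeq2 called 415, and 190 passed without the muscle-rich libraries.

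**Figure D3:**
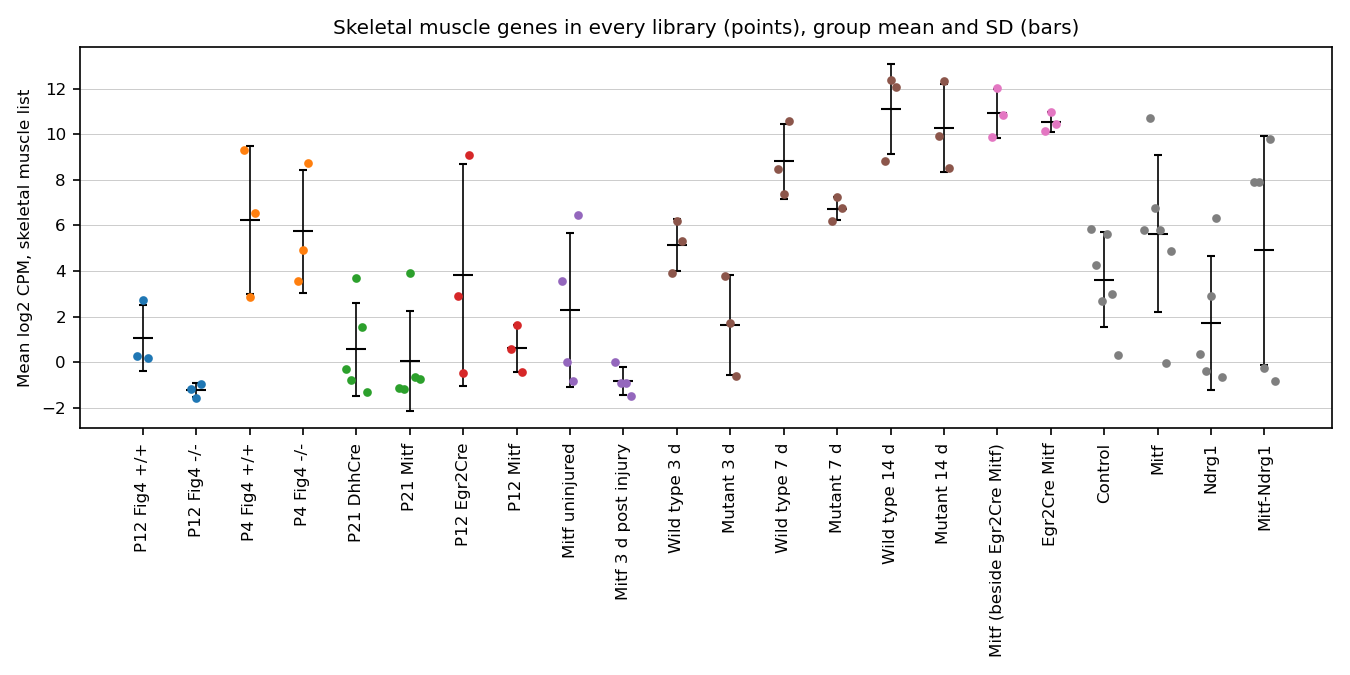
Mean log2 CPM of the skeletal muscle list (y axis) in each of the 82 libraries (points) of the 22 groups (x axis), with group means and SDs as bars. Values run from -1.48 to 0.0167 in injured nerves labelled Mitf and from 8.51 to 12.4 in wild type and Mutant nerves 14 days post injury, and Mitf-Ndrg1 replicates 1, 2 and 4 lie at 7.91, 7.89 and 9.78.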

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

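The tests of skeletal muscle and fat RNA, of nuclear RNA, of the Schwann cell and macrophage share, and the splits were chosen only after the result was seen; the tests of sex, of transcript length and GC content, and of the 3 interactions were planned.

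The interactions passed for 23 genes (Fig4 effect at P12 against P4) and 13 genes (Mutant effect over time after injury). That of the Mitf and Ndrg1 labels passed for 62. Splits of the libraries did not exclude chance for any.

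The first pattern was the response of Fig4 -/- nerves at P12, where the genes called higher had a median log2 change of 1.21 and those called lower one of -0.764, and where every Fig4 -/- library carried Y-linked counts and no Fig4 +/+ library did. Sex of the animals is argued against as the cause: at P21, where both sexes occurred in both groups, 242 of the higher genes had a median male minus female difference of 0.00958 (SE 0.0255) and 159 of the lower ones of -0.0412 (SE 0.025). Skeletal muscle RNA is argued against as the source of the size of the change: with the muscle score as a covariate the medians were 1.25 and -0.697, while the number of called genes dropped from 435 to 29 because the median SE of the higher genes went from 0.202 to 0.365. The splits of the 6 libraries number 10, too few for a share under 0.05, with 435 genes for the real split and at most 2 for another. Loss of Fig4, the explanation the design names, stays open, as do litter or strain differences between the genotypes, which were not tested.

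The second pattern was the 1117 genes higher in Mutant nerves 14 days post injury, led by the nuclear RNA Meg3; without Mutant replicate 2 the excess of higher genes was gone, with 2642 higher and 2317 lower. Skeletal muscle RNA is argued against as the whole cause, because 82.5% of these genes stayed called higher with the muscle score as a covariate, and so is transcript length and GC content, because 72.2% stayed called higher with an offset for both (94.7% of them had a length). Length was still related to the change, with a median log2 change of -0.15 in the shortest 20% and 0.274 in the longest 20% of transcripts. RNA retained in the nucleus, such as from a preparation richer in nuclei, cannot be told apart from a genotype effect: 7 other nuclear RNAs had a median change of 0.143 (interquartile range 0.965), below 0.924 for the called genes by less than their spread, while each Mutant library (3.27 to 3.37) scored above each wild type library (2.80 to 3.12). The splits of the 6 libraries number 10, too few for a share under 0.05, and the highest other split (wild type 1, Mutant 1 and Mutant 3 against the rest, the lower and higher muscle scores) called 3898 genes against 1314, which points to a structure of the samples; the Mutant genotype stays open and untested beyond these fits.

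The third pattern was the rise of endothelial and perineurial genes in Mitf-Ndrg1 over Ndrg1 libraries, with a median of 0.532 over 21 members. Skeletal muscle and fat RNA is argued against as the source of the size of the change: with both scores as covariates the median was 0.497, although the members past the test went from 12 to 2 as the median SE went from 0.133 to 0.153 and 19 genes passed in all. A lower share of Schwann cell and macrophage RNA would raise every other cell type alike. It cannot be told from a change of the perineurial (quartiles 0.58 to 0.931) or endothelial genes (0.257 to 0.555), as other lists differed. Mast cell (0.177 to 0.296), lymphocyte (-0.427 to 0.218) and fibroblast genes (0.17 to 0.559) lay below the perineurial range. Pericyte and smooth muscle genes (0.258 to 0.699) overlapped it, and erythrocyte (0.956 to 1.06) and adipocyte genes (1.70 to 2.25) lay above it. The splits counted all genes, not this pattern, and cannot exclude chance for it. Of 100, 2 with the real one reached 234 genes (highest other 552), which points to a further structure of the samples. An effect of the Mitf label on vessels and sheath in Ndrg1 nerves, which the design names, stays a hypothesis, beside differences in dissection, which were not tested.

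Single libraries stood apart from the rest of their group in 24 of 232 groups of values tested with Dixon's criterion, where chance alone gives about 1 in 20. Fig4 stood at 29.6 CPM in Mitf replicate 3 at P21 (others 24 to 25.6). In the table with Ndrg1, Mitf replicate 2 had 18.4 CPM of Fig4 (others 21.7 to 23.5) and mean log2 CPM of 10.6 for myelin (others 10.8 to 10.9), 7.76 for glycolysis (others 6.37 to 6.6) and 6.04 for pericyte and smooth muscle genes (others 5.08 to 5.42). Mitf replicate 4 stood at 3.09 for interferon response (others 2.75 to 2.87) and 8.16 for extracellular matrix genes (others 7.97 to 8.03), and Mitf replicate 6 at 3.31 for perineurial genes (others 3.98 to 4.08). Control replicate 5 stood at 3.22 for interferon response (others 2.76 to 2.92) and control replicate 1 at 3.81 for adipocyte genes (others 1.62 to 2.25). Mitf-Ndrg1 replicate 4 stood at 4.05 for the integrated stress response (others 3.67 to 3.78), Mitf-Ndrg1 replicate 2 at 2.59 for mast cell genes (others 3.26 to 3.46), and Ndrg1 replicate 2 at 4.23 for endothelial genes (others 4.45 to 4.51). In the injury table, injured replicate 2 stood at 5.71 for cholesterol synthesis (others 6.29 to 6.37) and injured replicate 1 at 6.70 for non-myelinating Schwann cell genes (others 5.38 to 5.44). Uninjured replicate 4 stood at -2.25 for neutrophil genes (others -2.95 to -2.84) and uninjured replicate 2 at 3.96 for adipocyte genes (others 5.05 to 5.16). At P21, DhhCre replicate 3 stood at 3.73 for macrophage genes (others 4.11 to 4.27), Mitf replicate 5 at 1.28 for adipocyte genes (others 3.82 to 4.19) and Mitf replicate 3 at 3.92 for skeletal muscle genes (others -1.18 to -0.632). Sex-linked genes stood low in uninjured replicate 4 (-1.37, others 2.56 to 2.78), injured replicate 4 (-1.52, others 2.52 to 2.75), control replicate 4 (-0.663, others 3.20 to 5.27) and Mitf-Ndrg1 replicate 2 (-0.996, others 3.14 to 4.70).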

How the results depend on the processing

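The skeletal muscle covariate, the removal of muscle-rich libraries and part of the left-out libraries of the Ndrg1 response were chosen after seeing the data; the other alternatives were planned. Of single genes under all alternatives 17071 values kept direction and side of the threshold, 1460 lost the call, 3 gained it and 22 reversed; of lists and sets 6350 kept both, 455 lost the call, 311 gained it and 4 reversed. RLE scaling left 1128 of 1136 genes and 445 of 450 lists and sets on their side, and no scaling moved the median of all genes by over 0.1. The estimated correlation ended most calls, 168 among 450 lists and sets called or not. Without a fold minimum 70 of 80 sets kept their side. Causes not given below were not tested.

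The replicate number as a block gave 0 genes for Fig4 at P4, 2 for the difference between the ages, 4 for DhhCre, 0 for Egr2Cre at P12, 856 for Mutant at 14 days and 1 for the genotype by time effect; other counts moved by less than 1.5 times, and 436 of 450 lists and sets kept their side. The numbers paired the libraries by correlation in the DhhCre and Egr2Cre Mitf tables alone. In the others a block takes up degrees of freedom; every Fig4 pair at P12 correlated best with its own number (0.00605 to 0.0549), a hint from the data, and no Egr2Cre pair at P12 did (-0.337 to -0.0973).

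DESeq2 called 922 genes for Fig4 at P12, 8 at P4 and 148 for the difference, 12 for DhhCre, 9 for Egr2Cre at P12, 242 and 2312 for Mutant at 7 and 14 days, 410 for genotype by time, 7 for Egr2Cre Mitf, 14 for Mitf against control, 750 for Mitf-Ndrg1 against Ndrg1 and 415 for the interaction. Without the low-count filter, which changes the number of genes tested, there were 1131 for Fig4 at P12, 4 for Egr2Cre at P12, 3 at 7 and 846 at 14 days. RLE scaling gave 13 for the difference between the ages and 2 at 7 days. A sex covariate gave 0 for Egr2Cre at P12 and 0 for Mitf against control; it was not run for the Fig4 tables, where no Fig4 +/+ library reached 1 CPM of Ddx3y. Fits of the compared groups alone, which have fewer degrees of freedom, gave 0 at 14 days, 3 for Mitf against control and 31 for Mitf-Ndrg1 against Ndrg1.

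The muscle covariate gave 29 genes for Fig4 at P12, 64 for the difference between the ages, 1068 for the injury table, 4177 for 14 against 3 days, 360 for genotype by time, 141 for Mitf-Ndrg1 against Ndrg1 and 96 for the interaction. Without muscle-rich libraries there were 13 for Fig4 at P4, 47 for the difference, 587 for Mitf-Ndrg1 against Ndrg1 and 190 for the interaction. Between 14 and 3 days the muscle covariate reversed Srebf2 (0.047), Rragd (-1.60), Pfkm (-0.34), Aldoa (-1.70), Ldha (-1.01), Tpi1 (-1.17), Erbb2 (0.027), Des (-0.57), Ucp1 (-1.31), Tnni2 (-0.49), Tnnc2 (-0.71), Acta1 (-1.31), Actn3 (-1.75), Tnnt3 (-1.94), Ckm (-2.15), Atp2a1 (-2.34) and Myh4 (-3.48), several of which define the covariate. Without muscle-rich libraries Mitf-Ndrg1 against control reversed for Chac1 (-0.54), Dusp1 (-0.013), Des (-0.65), Lipe (-0.0026) and Cidec (-0.18). At P4, leaving out Fig4 +/+ replicate 1 reversed the medians of myelin (-0.216; up to 0.26 without another library) and cholesterol synthesis (-0.108; up to 0.276) and of the sets lower after injury (-0.151; up to 0.24) and lower in Ndrg1 (-0.138; up to 0.205).

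With each library left out in turn, the counts ran from 146 to 709 for Fig4 at P12, 0 to 1 at P4, 5 to 26 for the difference, 0 to 2 for Egr2Cre at P12, 1816 to 4058 for injury, 0 to 11 at 7 and 139 to 4959 at 14 days, 1 to 146 for genotype by time, 1 to 3 for Mitf against control, 58 to 545 for Mitf-Ndrg1 against Ndrg1 and 20 to 252 for the interaction; the Ndrg1 response in Mitf-Ndrg1 (-0.128) ran from -0.171 to -0.0845, and was -0.0856 with genes chosen on even numbers and -0.221 without muscle-rich libraries.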

Other observations

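All tests in this part were chosen only after the result was seen.

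For injury, 1 of 35 splits of the libraries reached the real count (3365 genes against at most 3), so chance can be excluded unless the numbers are pairs. For Ndrg1 (9626 against at most 8406) and Mitf-Ndrg1 against control (9401 against at most 8092) 1 of 100 splits did each, so chance can be excluded. For Mitf against control 3 of 100 did, but the count of 1 gene was equalled by other splits (at most 1) and ended with a sex covariate, so it decides little. For the interaction of both labels 3 of 100 did (62 against at most 810). The highest split points to a structure of the samples, so this share cannot exclude chance. For the difference of the Fig4 effect between the ages 10 of 100 splits reached 23 genes (at most 508), and for genotype by time 11 of 100 reached 13 genes (at most 1216); chance cannot be excluded, and both point to a structure of the samples. For DhhCre 7 of 100 reached 2 genes (at most 250), so chance cannot be excluded. The 12 other splits that parted all 5 number pairs called at most 1 gene, while the 87 that parted fewer called up to 250. For the comparisons with 10 splits a share under 0.05 is out of reach. The real and the highest other count were 1 and 2 for Fig4 at P4, 0 and 0 for Mutant at 3 days, 0 and 10 at 7 days, and 9056 and 0 for 14 against 3 days. They were 2 and 2506 for Egr2Cre at P12, where the split of Egr2Cre 1, Mitf 2 and Egr2Cre 3 from the rest points to a structure of the samples. For Egr2Cre Mitf they were 0 and 7, and the 3 other splits that parted all 3 pairs called 0 while the 6 that parted fewer called up to 7.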
